A study of Mus with 17 samples.

How the data were processed

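Whole liver of 17 male mice was measured by bulk RNA sequencing, with 1 library per mouse. Per the labels, 8 mice had a western diet with fructose at 42 g/L in the drinking water and 9 had chow with plain water, for 52 weeks. The source name in the labels reads western diet for all 17 samples, whereas the treatment field gives 8 on western diet and 9 on chow, as the description of the series does; the treatment field was used. Replicate numbers follow the order of the samples in the labels, and no pairing of mice across diets is given. Per the labels' protocols, frozen liver was pulverised, RNA was taken with phenol and chloroform and purified on RNeasy columns, libraries were made with NEBNext Ultra kits, and they were read from both ends on a NovaSeq instrument.

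The deposited values are expected counts per gene symbol, 1 file per library, in steps of 0.5 and not scaled between libraries. Between 29.4% and 33.7% of all values in a library, those at 0 included, were not whole. Per the submitters' processing notes, STAR 2.4.1c, HOMER, FastQC and MultiQC and the mouse assembly mm10 were used; their options, the strand setting, the annotation release and the treatment of duplicate reads and of reads with several matches are not given in the sources used here. Overlapping and antisense genes, and near-identical gene copies, can therefore share reads. Each file held 24940 genes; 3 had no value in any file and were left out, which left 24937. Values were rounded to whole counts before the fits.

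Genes were kept by edgeR's filterByExpr with the diet as design, which left 13204. Two-sided tests were made with edgeR 4.0.16 (R 4.3.3): TMM factors, dispersions with robust estimation, glmQLFit and glmQLFTest on the design of diet alone, and Benjamini-Hochberg adjustment over all genes tested at 0.05. Log2 differences are western diet minus chow and were fitted with a prior count of 0.125; the SE is the log2 coefficient over the square root of the F statistic. CPM were computed with the TMM-scaled library sizes and are given as mean ± SD over the libraries of a diet. The common dispersion was 0.0360, a biological coefficient of variation of 19.0%. Library totals were 3604212 to 9071908.5 counts, and 3 counts, the upper limit that a count of 0 allows, were 0.331 to 0.832 CPM. In 2 tested genes every library held the same values as in another gene. The genes were matched by symbol to a RefSeq gene table of GRCm38.p6, the assembly also called mm10: 24297 of 24940 matched, and 12954 tested genes had a position.

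The 37 gene lists were fixed before the data were examined, from general knowledge of liver biology. They held 610 distinct tested genes, 17 of them in more than 1 list. Each list was tested with camera (limma 3.58.1) on the edgeR fit at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists, then with the correlation estimated for each list, and with fry. A list's members that rose or fell are those past the adjustment over all genes; the number past an adjustment over the list alone is given beside it. Genes named in the text were chosen by a rule of 3 parts: a fixed set of genes of the disease; the 10 genes that rose most and the 10 that fell most among those past the threshold, with an average log2 CPM of at least 1 and no overlap between the libraries of the diets; and up to 3 members of each list. The rule named 150 tested genes and Timp1, which was not tested. Some of the genes that the rule names are not reported here. Other genes were chosen after their values were seen.

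The distance of each library to the mean of its diet was compared between diets by permuting the labels over all 24310 labellings. Within a diet, the mean z score of the matrix list was correlated with that of 9 other lists, leaving out shared genes, with p-values from all orders of the libraries. They were adjusted over the 9 relations of a diet. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for these steps and the plots.

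Alternatives fixed in advance were size factors of the DESeq2 type (RLE), library size alone, scaling without the 50 most abundant genes, DESeq2 1.42.0, limma-voom, no low count filter, a filter of CPM of at least 1 in at least 8 libraries, fits without robust estimation, an adjusted p under 0.01, a test against a 1.5-fold change (glmTreat), 1 surrogate variable from svaseq (sva 3.50.0), and leaving out each of the 17 libraries in turn. For the distances the 500 most variable genes and the group median were tried, and for the relations the first principal component and RLE factors. Alternatives chosen after seeing the data were leaving out the libraries with pancreatic transcripts, the first principal component of the clock list as a covariate, and counts doubled in place of rounding. No paired analysis was possible because the labels pair no mice across the diets.

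The steps were first run on drawn counts of 12800 genes, of which 12605 were unchanged. They were drawn from the means of the chow libraries, the totals of all libraries and the trend of dispersion with abundance. Of genes changed 1.5-fold 75% were recovered (48 of 64), of those changed 2-fold 98.5% (65 of 66) and of those changed 4-fold 100% (65 of 65). Among the calls, 6 (3.26%) were false. Rises and falls were set in near equal number and no library was made outlying, whereas 48.4% of the real genes were called. These shares therefore do not give the error rate in the real data and do not test TMM scaling there. All 5 changed lists were called, and 1 of 30 lists that shared no gene with them was called. Those 30 lists could still hold single genes changed at random. Counts were drawn independently for each gene, so this does not give camera's error rate for correlated genes. For unrelated scores, 4.75% of 400 runs gave an exact permutation p under 0.05, and 7.0% of 200 runs did for groups of equal spread. For counts in proportion to the total, the slope of abundant genes was 1.02. It was 0.657 for counts computed with a ceiling per gene and without sampling noise. Real counts of Alb, 16683 to 33769, lay above that ceiling, so this setting does not describe the most abundant genes.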

Results

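RNA of whole liver was sequenced from 17 male mice of the inbred strain C57BL6/JBomTac. Of these, 8 mice had eaten a western diet and had drunk water with 42 g/L of fructose for 52 weeks, a regimen that the labels describe as bringing on an advanced fatty liver disease with inflammation. The other 9 mice were of the same age and had eaten standard chow and drunk plain water. All mice were fasted overnight before they were killed. The series concerns advanced steatohepatitis in the mouse and signalling of liver pericytes, and the comparison here asks which transcripts of the liver differed after 52 weeks on either diet.

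Each library held between 3604212 and 9071908.5 counts, with 6468850 ± 1756836 (SD, n = 8) on western diet and 6683599 ± 1136419 (SD, n = 9) on chow. Between 16120 and 17853 genes had a value above 0 in a library. A count of 0 allowed a level of up to 0.331 CPM in the deepest library and 0.832 CPM in the shallowest, the level of 3 counts, which covers counting error only. The 10 most abundant genes held 2.70% to 4.06% of the counts. No pair of libraries of a diet was alike within sampling noise: the chi-square per degree of freedom was 3.94 to 40.3 over the 36 chow pairs and 4.92 to 25.5 over the 28 western diet pairs. The series describes 8 and 9 mice, so each library was taken as 1 mouse and the p-values measure the spread between mice. The first principal component of the log2 CPM of all tested genes held 51.0% of the variance and separated the diets.

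**Figure D1:**
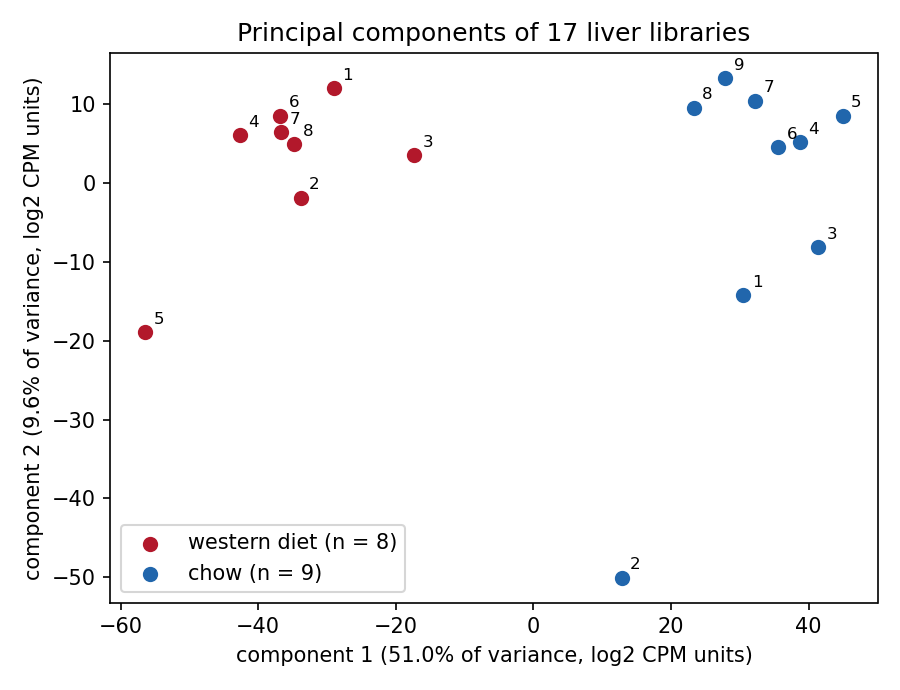
Scores of the 17 liver libraries on the first principal component (x axis, 51.0% of the variance) and the second (y axis, 9.57%) of log2 CPM over 13204 tested genes; each point is 1 library, coloured by diet and numbered by replicate. Western diet libraries lie between −56.4 and −17.3 on the first component and chow libraries between 12.8 and 44.9, and chow replicate 2 has the lowest score on the second component, −50.1.

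Western diet livers carried more transcript of scar matrix, of lipid-laden macrophages, of antigen presentation and of interferon response, and less of cholesterol synthesis and of fatty acid oxidation. Collagen Col1a1, the main protein of liver scars, rose 3.38-fold, the macrophage receptor Trem2 rose 7.13-fold, and squalene epoxidase Sqle, a regulated enzyme of cholesterol synthesis, was 4.099-fold lower (n = 8 and 9). Of these 6 groups of genes, only the macrophage list kept its call with an estimated correlation. Of 13204 genes tested, 3271 rose and 3122 fell at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted), 48.4% of those tested. At least 2-fold, 1183 genes rose and 151 fell. All 8 western diet libraries lay above all 9 chow libraries in 922 of the genes that rose, and below them in 667 of those that fell, while chance gives 0.0823 per 1000 tested genes in either direction. Of all calls, 51.2% were rises; with library size alone in place of TMM factors 4485 genes rose and 1615 fell, 73.5% rises, and the median log2 difference of all genes was 0.12 in place of −0.0091. Of the 37 gene lists fixed before the data were examined, 15 stood higher and 6 lower than other genes in camera, a test that sets a list against the rest, at a preset correlation of 0.01; 3 of the 21 calls were held with an estimated correlation. Without western diet replicate 5 and chow replicate 2, which carried transcripts of pancreas, 3155 genes rose and 2919 fell, an alternative chosen after seeing the data.

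Among genes whose libraries did not overlap between the diets and whose average log2 CPM was at least 1, the largest rises were those of Ephb2, a receptor for membrane-bound ephrins (41.4-fold, 27.8 ± 11.6 against 0.6295 ± 0.364 CPM, mean ± SD, adjusted p = 4.68e-09), and of Gipc2, an adaptor with a PDZ domain (36.1-fold). They were followed by Shc2, an adaptor of receptor kinases (32.8-fold, 23.9 ± 9.95 against 0.724 ± 0.308 CPM), Lrtm2 (23.3-fold), and Cyp2a4, a steroid hydroxylase that is higher in female than in male liver (21.7-fold, 54.8 ± 54.96 against 2.46 ± 0.6203 CPM, adjusted p = 2.55e-05). Pls1, an actin bundler of the brush border, rose 20.03-fold, Sdcbp2 17.5-fold, the neuronal calcium sensor Hpca 16.8-fold, and Folh1, a carboxypeptidase, 15.7-fold. Ubd, a ubiquitin-like protein induced by inflammatory cytokines, rose 16.2-fold (40.05 ± 18.4 against 2.44 ± 1.09 CPM, adjusted p = 2.81e-07). In 8 of these 10 genes the chow mean was at or under 0.832 CPM, so their fold rests on few counts in the chow libraries; Cyp2a4 and Ubd were above that level. The strongest fall among such genes was that of Cd163, the macrophage receptor that takes up haemoglobin bound to haptoglobin, which was 20.03-fold lower (2.39 ± 1.03 against 45.2 ± 9.28 CPM, adjusted p = 5.55e-11). The acyl-CoA thioesterases Acot3 and Acot1 were 12.1-fold and 5.56-fold lower, and the major urinary proteins Mup12 and Mup1, carriers of pheromones made by the liver, 11.2-fold and 7.46-fold lower. Susd4, an inhibitor of complement, was 7.41-fold lower, Fam19a2 6.72-fold, the protease Capn8 6.23-fold, and Hhip, which binds hedgehog ligands, 5.34-fold. Reads of Mup1 and Mup12, of Acot1 and Acot3, and of Cyp2a4 and Cyp2a5 can be shared between near-identical copies, so the split between the copies is uncertain.

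On the mouse assembly mm10, the genes of the plot of single genes lay as follows: Ephb2 on chromosome 4, 136647536 to 136836326, Ubd on chromosome 17, 37193892 to 37196101, Cd163 on chromosome 6, 124304636 to 124330529, Acot3 on chromosome 12, 84052144 to 84060400, Col1a1 on chromosome 11, 94936224 to 94953042, Acta2 on chromosome 19, 34240336 to 34255585, Trem2 on chromosome 17, 48346401 to 48352276, Sqle on chromosome 15, 59315092 to 59331193 and Cel on chromosome 2, 28555819 to 28563403. Of the other genes with the largest changes, Gipc2 lay on chromosome 3, 152093839 to 152165900, Shc2 on chromosome 10, 79617934 to 79637918, Cyp2a4 on chromosome 7, 26307192 to 26315088, Mup1 on chromosome 4, 60498012 to 60501960, Susd4 on chromosome 1, 182764044 to 182896596 and Hhip on chromosome 8, 79965850 to 80058060. Each span is that of the whole annotated gene, exons and introns together.

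**Figure D2:**
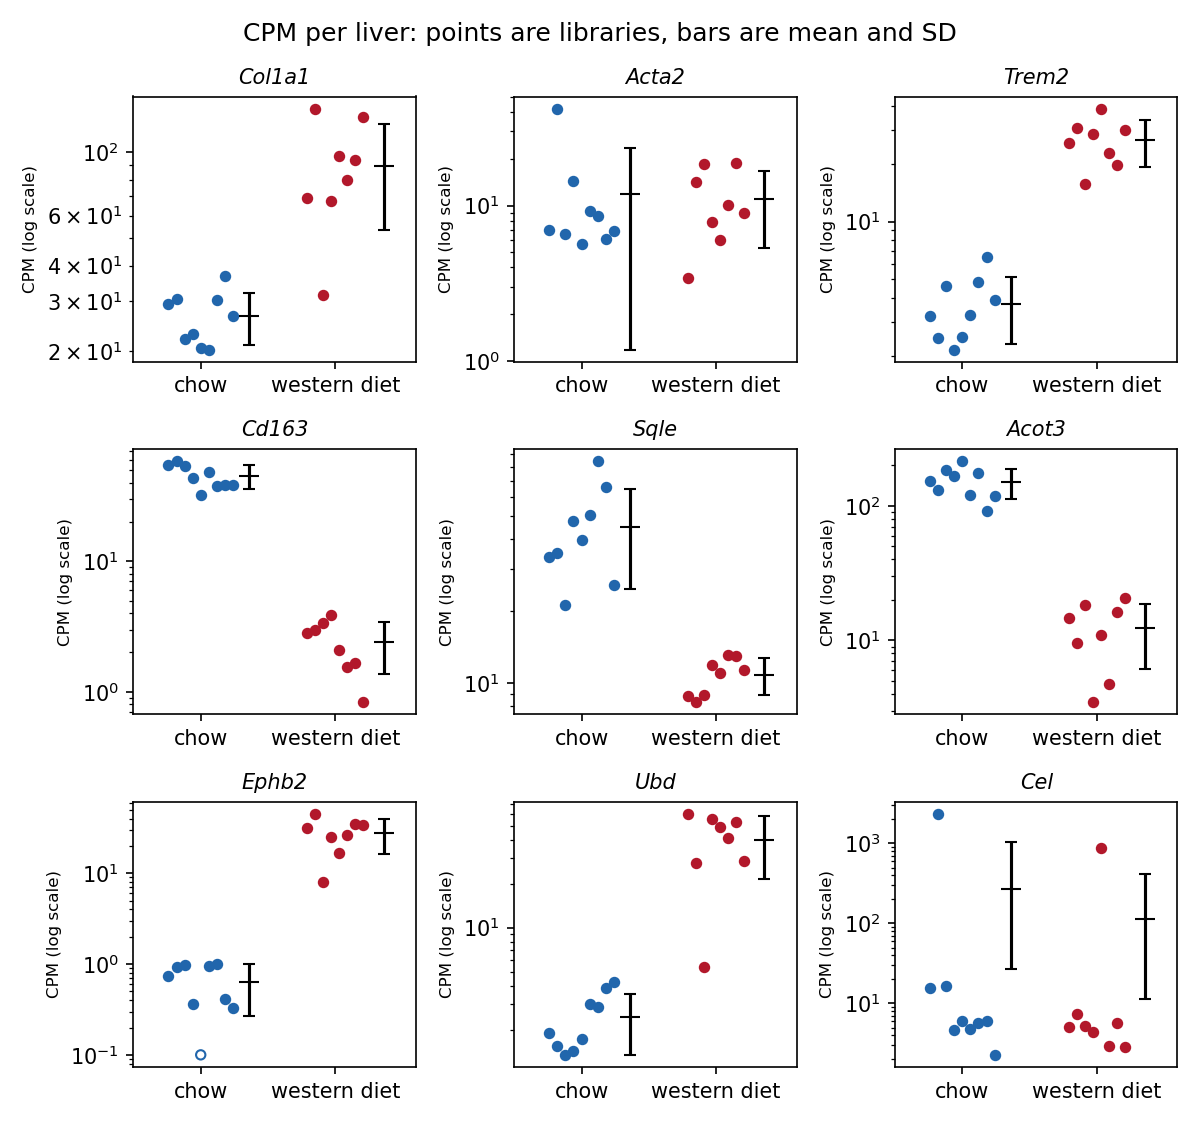
Level of 9 genes in each liver library in CPM on a log axis, with chow (n = 9) beside western diet (n = 8); points are libraries, bars are the mean and SD, an open point at 0.1 is a library at 0, and lower SD bars end at 10% of the mean where they would pass below it (Acta2 on chow, Cel on both diets). Trem2, Ephb2 and Ubd are higher and Cd163, Sqle and Acot3 lower on western diet, Acta2 overlaps between the diets, and Cel is high in western diet replicate 5 (868 CPM) and chow replicate 2 (2367 CPM).

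Genes of the extracellular matrix rose nearly throughout. Col1a1 went from 26.6 ± 5.59 to 89.4 ± 36.1 CPM (mean ± SD, n = 9 and 8; adjusted p = 7.06e-06), fibrillar collagens Col3a1 and Col1a2 rose 2.72-fold and 2.74-fold, and the collagen-binding proteoglycans lumican (Lum) and decorin (Dcn) rose 3.93-fold and 1.46-fold. Of 30 matrix genes 28 rose and 2 did not pass, Col5a3 (log2 difference −0.23 ± 0.13, ± SE) and fibronectin Fn1 (−0.13 ± 0.12); adjusted over the list alone 28 rose. Here and in the paragraphs that follow, members outside the naming rule, named because only a few of a list behaved that way, were chosen after their values were seen. The list stood higher than other genes (camera, adjusted p = 2.02e-11, median log2 difference 0.99; adjusted p = 0.2098 with an estimated correlation). Western diet replicate 3 was the western diet library nearest to chow, and the members that rose in the others lay in it at a median of 15.0% of the way from the chow mean to the mean of the other western diet libraries.

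Enzymes that crosslink and degrade matrix rose beside it. The macrophage elastase Mmp12 rose 9.998-fold (81.96 ± 25.2 against 8.21 ± 1.95 CPM, adjusted p = 3.08e-09), cathepsin K (Ctsk), a collagen-degrading protease, 2.72-fold, urokinase (Plau) 2.45-fold, and lysyl oxidase (Lox), which crosslinks collagen, 1.89-fold (adjusted p = 5.06e-04). Of 19 tested members of the list of crosslinking enzymes, proteases and inhibitors 16 rose and 3 did not pass, Mmp19, Loxl4 and Adamts1 (−0.16, 0.12 and 0.15 in log2); adjusted over the list alone 16 rose and 1 fell. As a list they stood higher (camera, adjusted p = 2.84e-08; adjusted p = 0.202 with an estimated correlation). The protease inhibitor Timp1, a usual marker of liver fibrosis, did not pass the low count filter and was not tested, with 4 to 44.5 counts on western diet and 1 to 7 on chow.

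Markers of activated stellate cells, the scar-forming cells of liver, rose without the contractile actin. The PDGF receptor Pdgfrb rose 2.696-fold (adjusted p = 2.27e-06), the growth factors Tgfb1 and Tgfb2, which drive matrix production, 1.77-fold and 3.35-fold, and 11 of 14 tested members of the myofibroblast list rose. The 3 that did not pass were Acta2, Myl9 and Ctgf (−0.093, −0.19 and 0.93 in log2); adjusted over the list alone 12 rose. Smooth muscle actin Acta2, the classic marker of myofibroblasts, was at 10.95 ± 5.65 against 11.8 ± 11.6 CPM (adjusted p = 0.875), and its direction changed with single choices. Chow replicate 2, with pancreatic transcripts, held 42.0 CPM against 5.67 to 14.4 CPM in the other chow libraries; the log2 difference was 0.46 without it, and 0.11 with limma-voom. The list stood higher than other genes (camera, adjusted p = 1.21e-04; adjusted p = 0.257 with an estimated correlation).

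Of the markers of quiescent stellate cells, more rose than fell. Cytoglobin Cygb, an oxygen-binding globin of stellate cells, rose 2.56-fold (adjusted p = 1.19e-07), the lectin Colec11 1.62-fold, Lrat, which stores vitamin A as esters, 1.52-fold, and reelin (Reln) 1.27-fold. Of 23 members 11 rose, 2 fell (Hhip, −2.42 ± 0.32 in log2, and the chemokine Cxcl12, −0.65 ± 0.10) and 10 did not pass, with the same counts adjusted over the list alone. The list stood higher by camera (adjusted p = 0.0292, median 0.36; adjusted p = 0.528 with an estimated correlation). The rise of Reln (adjusted p = 0.0448) was lost in 11 of the 17 fits that left out 1 library, with limma-voom (adjusted p = 0.0919) and with no low count filter (adjusted p = 0.0727), and with library size alone 17 members rose.

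Receptors of vasoactive and related signals that are found on pericytes moved both ways. Whole liver does not separate the cells, so changes in these receptors cannot be assigned to pericytes. The sphingosine phosphate receptor S1pr2 rose 1.98-fold (adjusted p = 1.35e-06) and the prostaglandin receptor Ptger1 1.55-fold, while the angiotensin receptor Agtr1a was 1.45-fold lower and Vipr1, the receptor of vasoactive intestinal peptide, 1.36-fold lower (adjusted p = 0.0108). The endothelin receptor Ednrb was at 24.8 ± 5.74 against 27.6 ± 5.59 CPM (adjusted p = 0.426). Of 28 tested receptors 15 rose, 6 fell and 7 did not pass; adjusted over the list alone 15 rose and 7 fell. The list did not stand apart by camera (adjusted p = 0.228), while fry, which asks whether the members move one way on balance, gave adjusted p = 0.00897. With library size alone 2 receptors fell in place of 6, and Vipr1 did not pass (adjusted p = 0.0728).

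**Figure D3:**
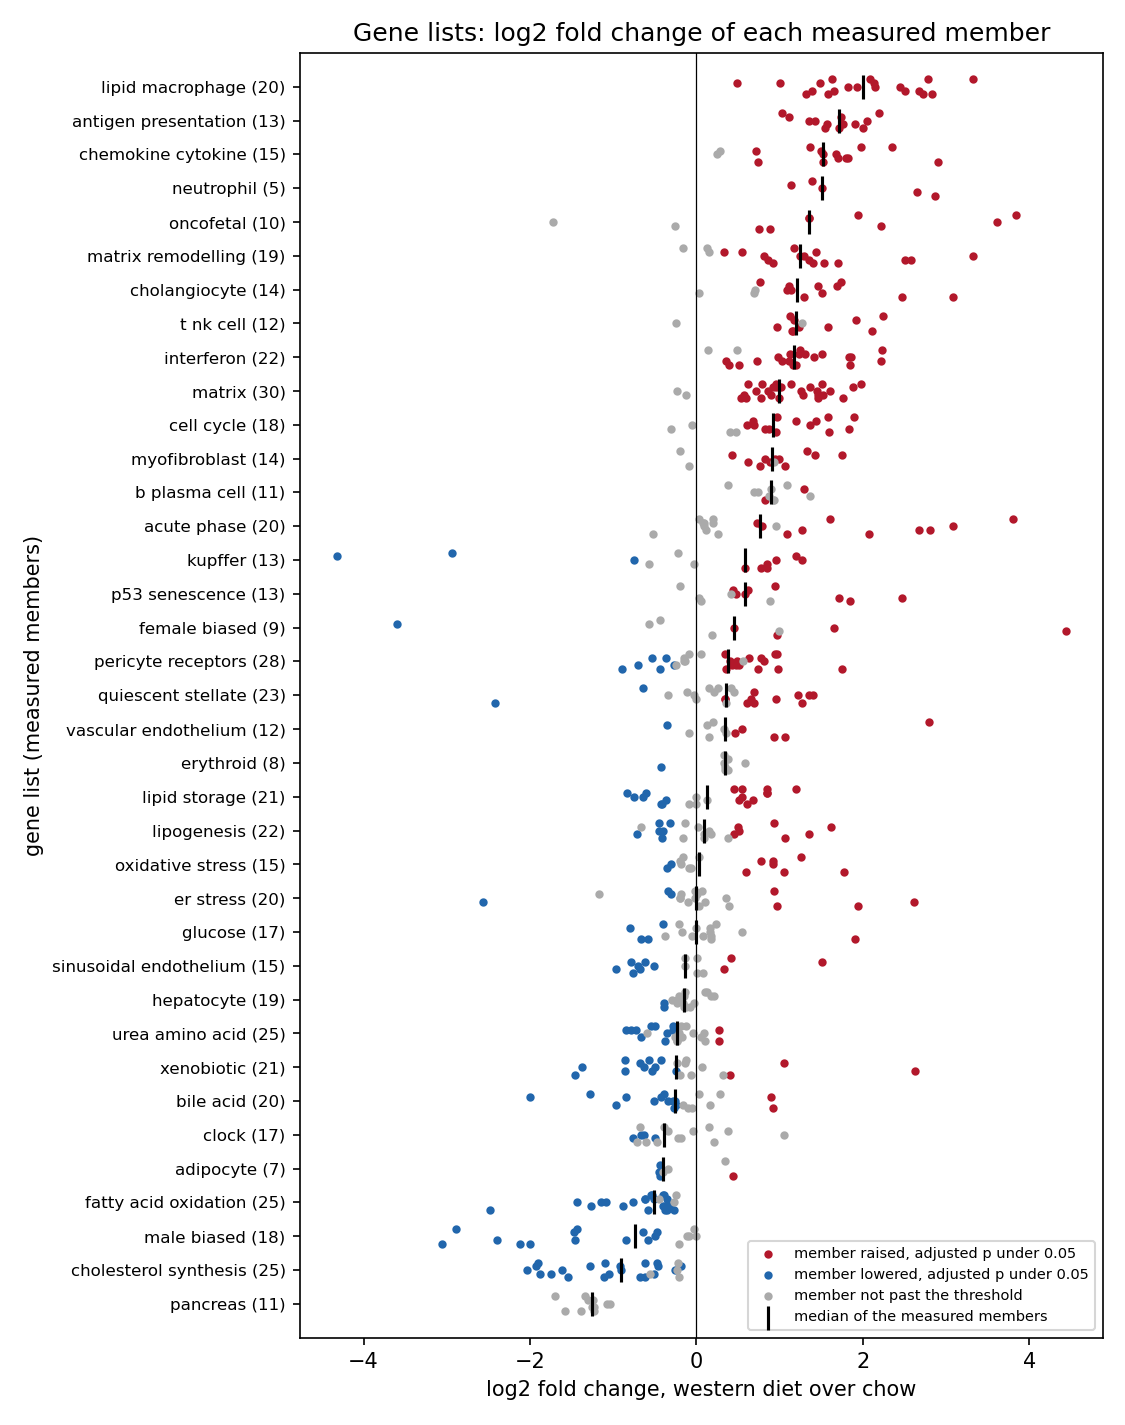
Log2 difference between western diet and chow (x axis) of each tested member of the 37 gene lists (y axis); each point is a gene, red if it rose, blue if it fell and grey if it did not pass an adjusted p of 0.05, and the black tick is the list's median. All 20 lipid-associated macrophage genes are red, with a median of 2.01, and 21 of 25 cholesterol synthesis genes are blue, with a median of −0.90.

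Markers of lipid-associated and monocyte-derived macrophages all rose. Trem2, a lipid-sensing receptor, went from 3.73 ± 1.40 to 26.4 ± 7.19 CPM (mean ± SD; adjusted p = 3.76e-09), the glycoprotein Gpnmb rose 6.39-fold, osteopontin (Spp1) 4.44-fold, the fungal pattern receptor Clec7a 6.62-fold, the lysosomal marker Cd68 2.998-fold and lipoprotein lipase (Lpl) 3.097-fold. In Trem2, Gpnmb and Spp1 every western diet library lay above every chow library. All 20 members rose, also adjusted over the list alone, and the list stood higher (camera, adjusted p = 2.96e-31, median 2.01; adjusted p = 0.00881 with an estimated correlation). All 20 rose in each of the 17 fits that left out 1 library.

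Markers of resident Kupffer cells, the macrophages of the liver sinusoid, moved apart. Cd163 was 20.03-fold lower, as above, and the scavenger receptor Marco and the ficolin Fcna also fell (−2.94 ± 0.71 and −0.75 ± 0.093 in log2), whereas Cd5l, an inhibitor of macrophage apoptosis, rose 2.29-fold, Il18bp, which binds the cytokine interleukin 18, by 1.26 ± 0.11 in log2, and the Kupffer cell lectin Clec4f 1.49-fold (222 ± 47.7 against 148 ± 16.1 CPM, adjusted p = 1.97e-04). Timd4, a receptor for dying cells on embryo-derived Kupffer cells, was at 9.78 ± 5.79 against 14.5 ± 3.61 CPM (adjusted p = 0.0881). Of 13 tested markers 7 rose, 3 fell and 3 did not pass (Timd4, Slc40a1 and C6), and the same counts were found adjusted over the list alone. The median was 0.58, the mean −0.18, and camera put the list higher without passing (adjusted p = 0.699). In western diet replicates 3 and 5 Marco was at 26.8 and 16.6 CPM against 0.837 to 2.31 CPM in the other western diet libraries, and Timd4 at 18.6 and 18.998 CPM; Timd4 passed without western diet replicate 3 (log2 difference −0.75, adjusted p = 0.0195) and without western diet replicate 5 (−0.79, adjusted p = 0.0139), and with limma-voom (adjusted p = 0.0279).

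T cell and natural killer cell genes rose from a low level. Cd8a, the coreceptor of cytotoxic T cells, went from 1.57 ± 1.0007 to 6.74 ± 6.07 CPM (mean ± SD; adjusted p = 0.00159), the chemokine Ccl5 rose 4.73-fold and the granule gene Nkg7 3.76-fold. Of 12 tested members 10 rose and 2 did not pass (Tox and Cd2); adjusted over the list alone 11 rose and 1 fell. As a list they stood higher (camera, adjusted p = 0.04201; adjusted p = 0.661 with an estimated correlation). Western diet replicate 5, with pancreatic transcripts, held the most Cd8a (20.4 CPM) and Nkg7 (13.4 CPM); without it 5 members rose and the log2 differences of Cd8a and Nkg7 were 1.59 and 1.35 in place of 2.11 and 1.91, without it and chow replicate 2 the list had an adjusted p = 0.0503, and DESeq2, which tested more members, had 19 rising.

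B cell genes were highest in 1 western diet library. Bank1, an adaptor of the B cell receptor, rose 1.77-fold (adjusted p = 0.0319) and Fcmr, the receptor of immunoglobulin M, 2.44-fold (adjusted p = 0.0432), and Jchain, which joins secreted immunoglobulins, was at 69.3 ± 72.2 against 53.8 ± 43.1 CPM (adjusted p = 0.657). Of 11 tested members 2 rose and 9 did not pass; adjusted over the list alone none passed edgeR's test, 4 rose at an unadjusted p under 0.05, 1 passed with DESeq2 and 2 with limma-voom. Camera did not set the list apart (adjusted p = 0.381). Western diet replicate 5 held 34.3 CPM of Cd79a and 31.1 CPM of Ms4a1, both components of the B cell surface, the highest of the 17 libraries. Bank1 and Fcmr no longer passed without that library (log2 differences 0.51 and 0.46 in place of 0.83 and 1.29, adjusted p = 0.105 and 0.271). Over the 17 fits that left out 1 library Bank1 was lost in 8 and Fcmr in 9, and Fcmr did not pass with DESeq2 or limma-voom (adjusted p = 0.337 and 0.0716). Leaving out single libraries gave from none to 5 rising members, 5 without chow replicate 8.

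Genes of neutrophils, of MHC class II and of cytokines rose. The alarmins S100a8 and S100a9 rose 7.27-fold and 6.27-fold (adjusted p = 1.18e-04 and adjusted p = 1.34e-04) and the receptor Csf3r 2.85-fold; all 5 tested neutrophil genes rose, also adjusted over the list alone (camera, adjusted p = 0.00271; adjusted p = 0.257 with an estimated correlation), and 10 rose with DESeq2, which tested more of them. The peptide loaders H2-DMb1 and H2-DMa rose 4.58-fold and 3.32-fold and Clec9a, a receptor of cross-presenting dendritic cells, 2.05-fold. All 13 tested antigen presentation genes rose, also adjusted over the list alone (camera, adjusted p = 2.02e-11; adjusted p = 0.117 with an estimated correlation). Among chemokines and cytokines Cx3cl1 rose 5.09-fold, Cxcl16 2.83-fold and the macrophage growth factor Csf1 1.64-fold. Of 15 tested members 13 rose and 2 did not pass (Il18 and Ccl9), with 13 adjusted over the list alone, and the list stood higher (camera, adjusted p = 4.49e-10; adjusted p = 0.0248 with an estimated correlation).

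Interferon-stimulated genes rose, and acute phase genes in part. The antiviral genes Oas2, Ifit2 and Oasl2 rose 4.64-fold, 3.61-fold and 3.55-fold (adjusted p = 6.92e-09 for Oas2). Of 22 members 20 rose and 2 did not pass (Igtp and Mx2); adjusted over the list alone 21 rose (camera, adjusted p = 1.77e-10; adjusted p = 0.2098 with an estimated correlation). In the acute phase list the iron-sequestering lipocalin Lcn2 rose 13.99-fold (186 ± 181 against 13.2 ± 7.26 CPM, adjusted p = 1.76e-05), the metalloreductase Steap4 3.05-fold and the interleukin receptor Il1r1 2.41-fold. Of 20 members 10 rose and 10 did not pass, with 10 adjusted over the list alone (camera, adjusted p = 0.0183; adjusted p = 0.661 with an estimated correlation). Western diet replicate 4 held the highest levels of this group, with 873 CPM of the acute phase apolipoprotein Saa1, 623 CPM of Lcn2 and 822 CPM of Steap4; without it the log2 difference of Lcn2 was 3.22 in place of 3.81. Copies of the serum amyloid A and orosomucoid genes can share reads, so single members such as Saa1 are uncertain.

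Of the hepatocyte markers, albumin and a regulator of hepatocyte genes fell and the others did not pass. Albumin (Alb) was 1.31-fold lower (adjusted p = 0.0116) and the transcription factor Hnf4a, a regulator of hepatocyte identity, 1.31-fold lower (adjusted p = 2.85e-04), and apolipoprotein B (Apob) was at 4150.4 ± 977 against 5074 ± 1267 CPM (adjusted p = 0.135; 0.0460 without western diet replicate 1). Of 19 tested members 2 fell and 17 did not pass, with 2 adjusted over the list alone; camera gave adjusted p = 0.1248, and the median log2 difference was −0.15. Counts of the most abundant genes rose less than in proportion to the library total: within a diet the slope of log2 count on log2 total was 0.557 for Alb and 0.594 for Apob. Without western diet replicate 1, the shallowest library, 7 members fell, without western diet replicate 3, 5, and with 1 surrogate variable 9.

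Markers of cholangiocytes, the cells of the bile ducts, rose. The chloride channel Cftr rose 8.498-fold (adjusted p = 1.45e-06), the tetraspanin Tspan8 5.55-fold, Pkhd1, a protein of the bile duct cilium, 2.21-fold and keratin Krt19 2.44-fold (8.19 ± 2.62 against 3.37 ± 3.98 CPM, adjusted p = 0.0146). Of 14 tested markers 11 rose and 3 did not pass, Spint1 and Krt23 among them; adjusted over the list alone 12 rose (camera, adjusted p = 3.22e-05; adjusted p = 0.298 with an estimated correlation). Chow replicate 2, with pancreatic transcripts, held 13.8 CPM of Krt19 against 0.944 to 2.77 CPM in the other chow libraries, and without it the log2 difference was 1.9955 in place of 1.29; keratins of this kind are also made in pancreatic ducts.

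Endothelial markers shifted within each list. Among sinusoidal markers Bmp2, a signal for iron balance in hepatocytes, was 1.73-fold lower (adjusted p = 5.59e-05), the nuclease Dnase1l3 1.54-fold and the lectin Clec4g 1.43-fold, whereas the scavenger receptor Stab2 rose 1.26-fold and Flt4 and Lyve1, also markers of lymphatic vessels, rose by 0.42 ± 0.15 and 1.51 ± 0.30 in log2. Of 15 members 3 rose, 7 fell and 5 did not pass, and adjusted over the list alone the counts were the same; camera gave adjusted p = 0.0649, with a range of 0.0287 to 0.177 when single libraries were left out. Among vascular markers Esm1, a proteoglycan of sprouting vessels, rose 6.96-fold (adjusted p = 7.25e-07) and Plvap, of fenestrated capillaries, 1.38-fold, and the receptor Ephb4 was 1.27-fold lower. Of 12 tested members 5 rose (Esm1, Plvap, Cd34, Angpt2 and Vwf), 1 fell and 6 did not pass; adjusted over the list alone 6 rose and 1 fell. Camera gave adjusted p = 0.134 and fry adjusted p = 0.00571, and with library size alone 9 rose.

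Cholesterol synthesis genes fell. Sqle was at 10.8 ± 1.91 against 44.7 ± 20.1 CPM (adjusted p = 2.77e-06), Cyp51, the demethylase of lanosterol, was 3.801-fold lower, the reductase Tm7sf2 3.36-fold and Hsd17b7 3.68-fold. Of 25 genes 21 fell and 4 did not pass, Mvd, Mvk and Sc5d among them; adjusted over the list alone 23 fell. The list stood lower (camera, adjusted p = 4.16e-13, median −0.90; adjusted p = 0.117 with an estimated correlation). The members that fell were as low in western diet replicate 3 as in the other western diet libraries, at a median of 105.6% of the way from the chow mean to theirs.

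Genes of fatty acid synthesis split. Thrsp, an activator of lipogenesis, rose 3.07-fold (adjusted p = 4.82e-05), the desaturase Scd2 2.56-fold, the pyruvate kinase Pklr 1.91-fold, the transcription factor Srebf1 2.09-fold (adjusted p = 0.00219) and the fatty acid synthase Fasn 1.36-fold (adjusted p = 0.02597), and the main desaturase of liver, Scd1, was at 4253 ± 818 against 3266 ± 1053 CPM (adjusted p = 0.108; 0.0311 with library size alone). Another 6 members, among them Me1, Fads1 and Fads2 (−0.72, −0.45 and −0.42 in log2), fell. Of 22 genes 7 rose, 6 fell and 9 did not pass; adjusted over the list alone 7 rose and 7 fell. The list did not stand apart by camera (adjusted p = 0.699), and fry's test for change in either direction gave adjusted p = 1.55e-11. Fasn no longer passed with limma-voom (adjusted p = 0.0538), and without western diet replicates 2, 7 or 8 in turn (adjusted p = 0.0579, 0.0539 and 0.0589).

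Genes of lipid droplets and lipid uptake likewise moved both ways. The droplet coat protein Plin3 rose 1.595-fold (adjusted p = 4.41e-05) and Cidec, which fuses droplets, 1.43-fold (adjusted p = 0.0379), whereas Fitm2, needed to form droplets, was 1.78-fold lower and the monoglyceride lipase Mgll 1.68-fold lower. Of 21 genes 10 rose, 7 fell and 4 did not pass, the same counts as adjusted over the list alone, and camera gave adjusted p = 0.884. Cidec was lost with no low count filter (adjusted p = 0.0707) and in 10 of the 17 fits that left out 1 library.

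Fatty acid oxidation genes fell. Acot1 went from 333 ± 129 to 59.993 ± 21.04 CPM (mean ± SD; adjusted p = 1.59e-06), the mitochondrial carnitine transferases Cpt2 and Cpt1a, the latter the gate of the pathway, were 1.698-fold and 1.32-fold lower (adjusted p = 1.44e-06 and adjusted p = 3.05e-04), and the carnitine carrier Slc25a20 1.53-fold lower. Of 25 genes 22 fell and 3 did not pass, the fasting hormone Fgf21 (21.4 ± 6.88 against 25.1 ± 14.5 CPM, adjusted p = 0.547), Pdk4 and Vnn1; adjusted over the list alone 22 fell. The list stood lower (camera, adjusted p = 4.14e-10, median −0.51; adjusted p = 0.2098 with an estimated correlation).

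Bile acid genes fell for the most part. Slco1a1, an uptake transporter that is higher in males, was 3.99-fold lower (adjusted p = 3.17e-06), Cyp8b1, which makes cholic acid, 1.96-fold lower (382 ± 98.2 against 748 ± 101 CPM, adjusted p = 1.60e-05) and the phospholipid exporter Abcb4 1.43-fold lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 259.8 ± 81.3 against 279 ± 241 CPM (adjusted p = 0.889), and its log2 difference of −0.10 was 0.039 with library size alone and 0.43 with limma-voom. Of 20 tested genes 12 fell, 2 rose (the sterol exporter Abcg5 and Abcc4) and 6 did not pass, with the same counts adjusted over the list alone. The list stood lower (camera, adjusted p = 0.00814; adjusted p = 0.288 with an estimated correlation); with library size alone 7 fell, and 1 rose without western diet replicate 1, 4 or 7 or chow replicate 7.

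Drug metabolising enzymes fell in larger part than they rose. The carboxylesterase Ces2a was 2.75-fold lower (adjusted p = 1.73e-07), the cytochrome P450 Cyp2c54, whose reads near-identical copies can share, 2.58-fold, and Por, the reductase that feeds electrons to microsomal P450 enzymes, fell too (−0.68 ± 0.071 in log2). Of 21 tested genes 11 fell, 3 rose (Gstm3, Nqo1 and Fmo5, by 2.62 ± 0.46, 1.05 ± 0.25 and 0.40 ± 0.10 in log2) and 7 did not pass, with the same counts adjusted over the list alone. As a list they stood lower (camera, adjusted p = 0.00516; adjusted p = 0.497 with an estimated correlation). Western diet replicate 1 held the highest mean log2 CPM of this list among western diet libraries, 8.71 against 7.92 to 8.19.

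Urea cycle and amino acid genes fell in part. Asl, an enzyme of the urea cycle, was 1.65-fold lower (348 ± 114 against 574 ± 81.2 CPM, adjusted p = 3.73e-04), Gldc, which breaks down glycine, 1.72-fold, and Tdo2, which opens the ring of tryptophan, 1.41-fold. Of 25 genes 10 fell, 2 rose (Glul and Prodh, by 0.27 ± 0.11 and 0.27 ± 0.11 in log2) and 13 did not pass; adjusted over the list alone 11 fell and 2 rose. The list stood lower (camera, adjusted p = 0.0101; adjusted p = 0.661 with an estimated correlation). Without western diet replicate 3, which held 619 CPM of Asl against 252 to 359 CPM in the other western diet libraries, 18 members fell, and the number that rose lay between none and 2 when single libraries were left out.

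In glucose metabolism Pck1, which commits carbon to glucose synthesis, was 1.59-fold lower (1268 ± 352 against 2014 ± 349.7 CPM, adjusted p = 6.75e-04) and the glycogen synthase Gys2 1.498-fold lower. The insulin signalling genes Irs2 and Insr also fell (−0.80 ± 0.21 and −0.40 ± 0.085 in log2). Of 17 genes 1 rose, 4 fell and 12 did not pass, with the same counts adjusted over the list alone. The list's median was −0.0056 and its mean 0.010, and camera put it lower without passing (adjusted p = 0.474); with library size alone 4 rose.

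Genes that are higher in male than in female liver fell, and those higher in female liver did not pass as a list. Susd4 and Slco1a1 were 7.41-fold and 3.99-fold lower and Cspg5 5.29-fold lower (adjusted p = 1.17e-05). Of 18 tested male-biased genes 13 fell and 5 did not pass (C8a, Egfr, Cyp4a12b, C6 and Nudt7), with 13 adjusted over the list alone; the list stood lower (camera, adjusted p = 2.96e-06, median −0.74; adjusted p = 0.255 with an estimated correlation). Of 9 tested female-biased genes 4 rose (Cyp2a4, Atp6v0d2, Slc22a27 and Fmo2), 1 fell (Acot3) and 4 did not pass; adjusted over the list alone 4 rose and 2 fell, and camera gave adjusted p = 0.862. Atp6v0d2, which is also in the macrophage list, rose 3.15-fold. From 1 to 3 female-biased genes fell when single libraries were left out, 3 without western diet replicate 5 or 8, and 5 with DESeq2.

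Stress genes changed singly more than as groups. Atf3, a transcription factor of the stress response, rose 6.15-fold (18.9 ± 4.67 against 3.08 ± 0.832 CPM, adjusted p = 1.83e-09) and Ddit3 (CHOP) 1.96-fold, while asparagine synthetase Asns was 5.94-fold lower (adjusted p = 2.92e-04). Of 20 genes of the unfolded protein and integrated stress response 4 rose (Atf3, Chac1, Ddit3 and Trib3), 3 fell (Asns, Ern1 and Ppp1r15a) and 13 did not pass, as they did adjusted over the list alone. The median of this list was −0.0028, its mean 0.12, and camera put it higher without passing (adjusted p = 0.651); 1 fell with library size alone and 5 with 1 surrogate variable. Of the oxidative stress genes, glucose-6-phosphate dehydrogenase (G6pdx) rose 1.899-fold (adjusted p = 1.60e-05) and haem oxygenase Hmox1 1.72-fold, and the mitochondrial dismutase Sod2 was 1.24-fold lower. Of 15 tested, 7 rose, 2 fell (Sod2 and Gsr) and 6 did not pass, the same adjusted over the list alone (camera, adjusted p = 0.594); 4 fell without western diet replicate 1.

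Proliferation and p53 genes rose. Mki67, a marker of cycling cells, went from 5.14 ± 3.54 to 14.99 ± 7.76 CPM (mean ± SD; adjusted p = 8.77e-04), the mitotic genes Cdk1, Cdc20 and Ccnb2 rose 2.98-fold, 3.704-fold and 2.58-fold, and 14 of 18 tested cell cycle genes rose and 4 did not pass (Tk1, Aurka, Birc5 and Rrm2); adjusted over the list alone 15 rose (camera, adjusted p = 3.41e-04; adjusted p = 0.316 with an estimated correlation). The p53 target Eda2r rose 3.58-fold (adjusted p = 6.30e-06), the stress hormone Gdf15 5.54-fold and Ccng1 1.39-fold. Of 13 tested members of the p53 and senescence list 8 rose and 5 did not pass (Bbc3, Mdm2, Sesn1, Trp53inp1 and Cdkn1a), with 8 adjusted over the list alone (camera, adjusted p = 0.00138; adjusted p = 0.2098 with an estimated correlation). Cdkn1a, the p21 cell cycle inhibitor, was at 47.0 to 113 CPM on western diet. It was at 127 and 138 CPM in chow replicates 1 and 2, which were low in the clock gene Dbp (13.0 and 8.25 CPM). Chow replicate 3, which held as little Dbp (12.9 CPM), had 30.1 CPM of Cdkn1a, and the remaining chow libraries had 6.05 to 21.7 CPM. Apart from chow replicates 1 and 2, every chow library thus lay below every western diet library.

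Fetal liver and tumour genes rose. The noncoding RNA H19 rose 12.2-fold (9.44 ± 3.91 against 0.7805 ± 0.421 CPM, adjusted p = 4.93e-08), the transcription factor Sox4 3.84-fold, and alpha-fetoprotein (Afp) 1.84-fold (3.29 ± 1.25 against 1.74 ± 0.558 CPM, adjusted p = 0.00697). Of 10 tested members 8 rose and 2 did not pass (Spink1 and Gpc3), with 8 adjusted over the list alone, and the list stood higher (camera, adjusted p = 5.46e-07, median 1.36; adjusted p = 0.02895 with an estimated correlation). Scd2 belongs to this list and to that of fatty acid synthesis.

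Clock genes were lower in part. The output factor Hlf was 1.54-fold lower (adjusted p = 7.91e-05), Cry2 1.59-fold and Clock 1.41-fold lower, and 4 of 17 genes fell (these and Tef) and 13 did not pass, with 4 adjusted over the list alone. Camera gave adjusted p = 0.228 and fry adjusted p = 0.0265. Libraries of a diet differed in this group: Dbp ranged from 8.25 to 203 CPM over chow and from 10.8 to 88.8 CPM over western diet, and chow replicates 1, 2 and 3 held 8.25 to 13.0 CPM. With the first component of the clock list as a covariate, chosen after seeing the data, 3 clock genes rose and 6 fell. The covariate was built from these same genes, so the 2 counts are no separate evidence on them.

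Markers of blood, fat and pancreas were measured for tissue carried along with liver. Alas2, of haem synthesis in red cells, was 1.34-fold lower (adjusted p = 4.03e-04), and globins Hbb-bs and Hbb-b1, whose reads can be shared, differed by 0.33 ± 0.16 and 0.33 ± 0.16 in log2 (adjusted p = 0.0914 and adjusted p = 0.0922). Of 8 tested erythroid genes 1 fell and 7 did not pass, with 1 adjusted over the list alone (camera, adjusted p = 0.684, median 0.34); 7 rose without chow replicate 7, 2 without western diet replicate 7 and 2 with library size alone. Among adipocyte markers the receptor Adrb3 rose 1.36-fold and the fat hormones Adipoq and Lep were 1.36-fold and 1.35-fold lower. Of 7 markers 1 rose, 3 fell (Adipoq, Lep and Plin1) and 3 did not pass; adjusted over the list alone 1 rose and 4 fell (camera, adjusted p = 0.518). Without western diet replicate 5, 6 or 8 or chow replicate 1 in turn, 1 fell, without western diet replicate 3 or 8 or chow replicate 2, 2 rose, and with library size alone none fell, 2 rose, and Adipoq and Lep had an adjusted p = 0.0978 and 0.0791.

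Pancreatic enzyme transcripts set 2 libraries apart, 1 of each diet. All 11 tested acinar markers lay at least 5-fold above the median of all libraries in chow replicate 2 and in western diet replicate 5, where they held 1.64% and 0.522% of the counts, against 0.0165% to 0.0627% in the other 15. Carboxyl ester lipase Cel was at 2367 and 868 CPM there. Between the diets none of the 11 markers passed edgeR's test, nor did any at an unadjusted p under 0.05, with DESeq2 or with limma-voom, also adjusted over the list alone (camera, adjusted p = 0.594, median −1.26). Log2 differences were −1.25 ± 1.73 for Cel, −1.39 ± 1.02 for chymotrypsinogen Ctrb1 and −1.23 ± 0.99 for elastase Cela2a. Without western diet replicate 5, 8 markers fell (Cel −5.83 and Ctrb1 −2.59 in log2 among them, with Cela2a at −2.40 not passing), and without chow replicate 2, 1 rose (Cel 3.91, with Ctrb1 at 0.80 and Cela2a at 0.87).

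No difference was detected between the diets in how much their livers differed from each other. The distance of a library to the mean of its diet over all tested genes was 0.291 ± 0.0735 (root mean square of log2 CPM, SD, n = 8) on western diet and 0.315 ± 0.0672 (SD, n = 9) on chow. The difference of −0.0238 was within the spread between libraries (2-sided exact permutation test over 24310 labellings, p = 0.5002). In each diet the library with pancreatic transcripts lay farthest. Chow replicate 2 was at 0.473 (others 0.258 to 0.354) and western diet replicate 5 at 0.404 (others 0.216 to 0.383). The comparison was not made without them.

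Within each diet, the score of the matrix genes was set against 9 other lists. On chow, livers with more matrix transcript had more myofibroblast transcript: Pearson's r = 0.969 (n = 9, 2-sided exact permutation p = 9.65e-05, adjusted p = 0.000868 over 9 relations) and Spearman's rho = 0.867 (exact permutation p = 0.00451, adjusted p = 0.0406). Without chow replicates 2 and 5, the farthest from the median matrix score, r was 0.936. On western diet none of the 9 relations passed after adjustment (n = 8): r was 0.852 for quiescent stellate markers (exact permutation p = 0.0138, adjusted p = 0.0722; rho = 0.619, exact p = 0.115), 0.777 for myofibroblast markers (exact permutation p = 0.0216, adjusted p = 0.0722; rho = 0.738, exact p = 0.0458) and 0.7602 for cholangiocyte markers (exact permutation p = 0.0241, adjusted p = 0.0722; rho = 0.643, exact p = 0.0962). It was −0.737 for hepatocyte markers (exact permutation p = 0.0405, adjusted p = 0.0911; rho = −0.619, exact p = 0.115) and 0.675 for cell cycle genes (exact permutation p = 0.0701, adjusted p = 0.105; rho = 0.762, exact p = 0.0368). With the first principal component as the score, 4 relations passed: quiescent stellate (r = 0.968, adjusted p = 0.00402), myofibroblast (0.869, adjusted p = 0.0112), lipid-associated macrophage (0.838, adjusted p = 0.0112) and cholangiocyte genes (0.789, adjusted p = 0.0356). With the mean score, lipid-associated macrophage genes had r = 0.693 (exact permutation p = 0.0539, adjusted p = 0.0970). Western diet replicates 3 and 1 were the farthest from the median matrix score. Without them r of the mean scores was 0.328, 0.545 and 0.502 for stellate, myofibroblast and cholangiocyte markers, over a narrower range of the matrix score. It was then 0.258 for lipid-associated macrophage genes, −0.213 for hepatocyte markers and 0.460 for cell cycle genes. On western diet the hepatocyte score was highest in replicate 1 (1.14), the shallowest library. That score was −0.931 in replicate 7, the deepest library of the diet, and lowest in replicate 5 (−1.05). Counts of the most abundant genes, Alb among them, rose less than in proportion to the library total, as above. Depth may therefore contribute to the hepatocyte relation, and its share was not tested. The relations of the diets were not tested against each other.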

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

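The test that split the libraries otherwise, 3 of the 4 tests on western diet replicate 3 and the ceiling and macrophage tests below were chosen only after the results were seen. A library was singled out where its gap to the nearest other library of its diet was large against the range of that diet (Dixon's test at 95%). This held in 47 of 376 sets of values, and chance gives 18.8. Western diet replicate 3 held 15 of them, western diet replicate 5 held 14 and chow replicate 2 held 8. The others were in chow replicate 8 (3), western diet replicates 1 and 4 (2 each), and chow replicates 5, 6 and 9 (1 each). Sets that share genes or libraries are not independent. Of 100 splits of the 17 libraries into 8 and 9, the split by diet was the only 1 with as many genes called, 6393. The highest other split had 1717, with 1 western diet library in its group of 8, so it nearly repeated the split by diet. The median of the other splits was 0. Mixed splits put the diet difference into the spread within groups, so their few calls were largely fixed in advance and the test adds little.

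Western diet replicate 3 was singled out with values toward chow in genes that rose. It was the lowest western diet library in Spp1 (158.8 CPM, others 281 to 432), Afp (0.930, others 2.61 to 5.10), Gipc2 (1.49, others 6.64 to 21.5), Shc2 (5.95, others 18.9 to 41.4), Pls1 (4.28, others 12.7 to 24.0), Sdcbp2 (2.60, others 11.1 to 31.6) and Ubd (5.39, others 27.9 to 60.4). It was also lowest in Mmp12 (31.6, others 64.6 to 112), Cygb (42.4, others 61.8 to 84.6), Tspan8 (6.32, others 13.1 to 20.3), Oasl2 (13.0, others 23.0 to 33.7) and H19 (2.60, others 7.65 to 15.7), and in the mean log2 CPM of the oncofetal list (3.16, others 3.70 to 4.19). It was the highest in Hhip (3.72, others 0.283 to 1.05) and Asl (619, others 252 to 359).

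For this library, a wrong diet label is argued against, because 67.9% of 1243 genes that rose at least 2-fold in the others (844 genes) lay above the highest chow library. RNA of a chow liver mixed in would bring every group of genes closer to chow, and is argued against by the cholesterol synthesis list, which lay at 105.6% of the way (95% bootstrap interval 91.6% to 111.0%), with 87.1% to 108.9% in the other western diet libraries. The lowered genes lay farther along the way than the raised ones by 27.8 percentage points (20.6 to 38.3). This decides nothing, since the gap was 26.4 in western diet replicate 1. Both bootstrap intervals resample genes, so they measure the spread among genes and not between livers. A milder response of that liver would leave the raised genes part of the way, and they lay at a median of 57.2%. The other western diet libraries lay at 73.5% (replicate 1) to 164.7% (replicate 5). The genes were chosen in a fit without replicate 3, which can lower its share against the others. A milder response remains a hypothesis, since it was found and tested on the same data. Matrix (15.0%), cholangiocyte (28.8%) and interferon genes (41.7%) lay nearer to chow in it than fatty acid oxidation genes (104%).

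Western diet replicate 5 was singled out in pancreatic and lymphocyte genes. It was highest in Cel (868 CPM, others 2.84 to 7.30), Ctrb1 (502, others 31.2 to 76.8), Cela2a (482, others 32.9 to 67.5), Nkg7 (13.4, others 1.49 to 3.72), Fcmr (19.3, others 1.83 to 3.98), H2-DMa (41.4, others 18.4 to 26.4) and Cxcl16 (68.5, others 45.9 to 53.2). The mean log2 CPM was also highest in the pancreas list (8.76, others 3.53 to 4.62), the T and natural killer cell list (3.86, others 1.40 to 2.45) and the antigen presentation list (5.50, others 4.59 to 4.95). It was lowest in Mup1 (0.921, others 3.72 to 10.8), Slc25a20 (159, others 206 to 243), Gldc (114, others 197 to 305) and Sod2 (196, others 223 to 248).

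Chow replicate 2 was highest among chow libraries in Cel (2367 CPM, others 2.28 to 16.4), Ctrb1 (1949, others 35.6 to 125), Cela2a (1656, others 30.1 to 112), Acta2 (42.0, others 5.67 to 14.4), Krt19 (13.8, others 0.944 to 2.77) and Eda2r (3.27, others 0.770 to 1.46). The same held for the mean log2 CPM of the pancreas list (10.4, others 3.41 to 5.52) and the cholangiocyte list (3.20, others 1.18 to 2.01). Chow replicate 8 was lowest in Vipr1 (39.1, others 66.7 to 93.8) and highest in Mki67 (14.2, others 2.68 to 5.20) and the cell cycle list (2.47, others 1.83 to 2.13). Chow replicate 6 was lowest in Spp1 (49.7, others 67.1 to 89.1), chow replicate 9 in Adipoq (10.4, others 15.98 to 24.3), and chow replicate 5 in Ephb2 (0, others 0.325 to 0.990). Western diet replicate 1 was lowest in Ednrb (13.0, others 21.8 to 31.2) and highest in the xenobiotic list (8.71, others 7.92 to 8.19). Western diet replicate 4 was highest in Steap4 (822, others 214 to 383) and the acute phase list (9.14, others 7.26 to 8.04).

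Abundant genes rose less than in proportion to the library total: the median slope of log2 count on log2 total within a diet was 0.565 for genes with a mean count of at least 8000 and 1.17 for those of 100 to 500. Less hepatocyte RNA in the deeper libraries would lower the slope of scarcer liver genes too. It is argued against by members of the liver lists at 100 to 1000 counts, whose slope was 1.27 (95% bootstrap interval 1.15 to 1.35, 32 members). These members share the same libraries, so their slopes are not independent and the interval may understate the spread between livers. For genes with a mean count of at least 8000 the slope was 0.573 on western diet and 0.546 on chow. Since it was fitted within diets, the diet was not tested as its cause. Reads counted a limited number of times per position, as when duplicates are removed, could give such a slope and remain open, and no step of that kind is named in the sources used here.

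The Kupffer markers moved apart. A loss of resident Kupffer cells alone would raise none of them, and 7 rose. A lower share of hepatocyte RNA alone would raise them alike, and markers past the threshold ranged over 5.59 in log2. Both values restate the pattern and were known when the tests were chosen, so they are no separate evidence. They also do not tell how many resident cells remained. Recruited macrophages in place of resident ones would raise the lipid-associated macrophage list, whose median log2 difference was 2.01. That rise was already known when the test was chosen. It also does not tell whether recruited cells replaced resident ones or were added to them, so the test does not decide. Whether the same cells changed their expression remains open, since whole liver does not separate the cells.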

How the results depend on the processing

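Tests without western diet replicate 5 and chow replicate 2, with the clock covariate and with doubled counts were chosen only after the results were seen. Where a result changed below, the cause was not tested unless a reason is given. All genes called both in the main setting and in an alternative kept their direction. Of the gene counts, the 1.5-fold test gave 1108 rising and 195 falling genes, since it asks for a larger change. Library size alone gave 1615 falling genes, DESeq2 1776 and 238 that rose or fell at least 2-fold, and no low count filter 1811 and 289, the last 2 with more genes tested. Leaving out single libraries gave 3066 to 3361 rising and 2816 to 3253 falling genes, and 1015 to 1287 and 142 to 180 at least 2-fold.

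Of 150 named genes tested, 137 passed the threshold, and none of these reversed. Apart from the stricter threshold and the 1.5-fold test, 8 were lost under some alternative (Reln, Vipr1, Fasn, Cidec, Bank1, Fcmr, Lep and Adipoq); 11 were lost at an adjusted p under 0.01 and 48 under the 1.5-fold test. Of those that had not passed, 7 passed under some alternative. Genes that had not passed changed direction as follows. Acta2 was at 0.030 in log2 with library size alone, 0.11 with limma-voom and 0.57 without western diet replicate 5 and chow replicate 2, and at −0.26 to 0.46 when single libraries were left out. Cyp7a1 was at 0.039 with library size alone, 0.43 with limma-voom and 0.10 with the clock covariate (−0.26 to 0.24). Jchain was at −0.12 without western diet replicate 5 and chow replicate 2 (−0.12 to 0.74), and Cel at 1.596 with the clock covariate (−5.83 to 3.91). Ctrb1 ranged from −2.59 to 0.80 and Cela2a from −2.40 to 0.87. Western diet replicate 5 and chow replicate 2 held most of the pancreatic transcripts.

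With an estimated correlation, 18 of 21 list calls were lost, since wider variance of a list's mean is allowed. The adjusted p was 0.210 for matrix, interferon, fatty acid oxidation and p53 genes, 0.202 for matrix remodelling, 0.257 for myofibroblast and neutrophil genes, 0.528 for quiescent stellate genes and 0.298 for cholangiocyte genes. It was 0.661 for T cell, acute phase and urea cycle genes, 0.117 for antigen presentation and cholesterol synthesis, 0.288 for bile acid, 0.497 for xenobiotic, 0.255 for male-biased and 0.316 for cell cycle genes. With fry, which does not set a list against other genes, 3 lists passed that camera did not: pericyte receptors (adjusted p = 0.00897), vascular endothelium (0.00571) and clock (0.0265). The T cell list was at 0.0503 without western diet replicate 5 and chow replicate 2. Leaving out single libraries moved camera's adjusted p across 0.05 for hepatocyte (0.0287 to 0.239), sinusoidal (0.0287 to 0.177), vascular (0.0459 to 0.197) and T cell genes (0.0161 to 0.0645).

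Of 1036 numbers of rising or falling members of a list under alternatives, 100 moved more than 1.5-fold, and 66 of 1258 did when single libraries were left out. The comparison of distances within diets did not pass with 500 variable genes (exact permutation p = 0.465) or with the median (exact permutation p = 0.516). With the first principal component as the score, 4 relations with the matrix score on western diet passed: quiescent stellate (r = 0.968, adjusted p = 0.00402), myofibroblast (0.869, 0.0112), lipid macrophage (0.838, 0.0112) and cholangiocyte genes (0.789, 0.0356). At the depth of 3604212 to 9071908.5 counts, genes under about 0.832 CPM were measured with a few counts or not tested.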

Other observations

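The test on sex-biased genes was chosen only after the result was seen. Livers of the same diet differed in their clock genes. Dbp, an output of the circadian clock, ranged from 8.25 CPM in chow replicate 2 to 203 CPM in chow replicate 9, and Per3 from 6.43 CPM in chow replicate 1 to 56.0 CPM in chow replicate 9. Npas2, which peaks at the opposite phase, was at 12.9 and 13.4 CPM in chow replicates 1 and 2. In the other chow libraries it was at 0.651 to 3.55 CPM, below all western diet libraries (5.23 to 16.4 CPM), though it did not pass between the diets. On western diet Dbp ranged from 10.8 CPM in replicate 4 to 88.8 CPM in replicate 7. The hours at which the mice were killed are not given in the sources used here. A difference in hour between the diets therefore cannot be told apart from the diet.

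Lymphocyte genes differed between livers of a diet too. On western diet Cd79a was at 34.3 CPM in replicate 5, at 13.5 CPM in replicate 7 and at 3.65 to 8.18 CPM in the others, and on chow at 18.7 CPM in replicate 8 and at 1.91 to 9.69 CPM in the others. Saa1, an apolipoprotein of the acute phase, was at 873 CPM in western diet replicate 4 and at 95.6 to 255 CPM in the other western diet libraries, and Lcn2 at 623 CPM there and at 61.7 to 209 CPM in the others. Marco was at 138 CPM in chow replicate 6 and at 15.4 to 59.8 CPM in the other chow libraries.

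Genes that are higher in male liver fell, which raised the hypothesis of a shift toward the female pattern. The genes higher in female liver did not stand apart as a list (adjusted p = 0.862 by camera), with 4 that rose and 1 that fell of 9 tested, so a shift toward the female pattern may or may not underlie the fall, and the test does not decide.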
